A study of Homo sapiens with 3 samples.

How the data were processed

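Total RNA of HT29 cells, an established human colorectal cancer cell line, was measured on 1-colour oligonucleotide arrays after 24 h in medium with DMSO, the solvent control, or with a linderapyrone derivative at 5 or 20 µM. There were 3 arrays in all, 1 per group. The sample titles give the doses in mM, while the treatment labels and the sample descriptions give them in µM; µM was used. Per the labels' protocols, RNA was isolated with a miRNeasy kit, amplified as amino allyl aRNA, coupled to a dye and hybridised to Toray arrays. Whether the 3 cultures were grown, extracted and hybridised together is not given in the sources used here.

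Per the file headers, each array's deposited scanner file holds the median brightness of every spot, an intensity on a linear scale with no background taken off. The headers also state that each array was read at 3 gains, which they relate to each other by straight lines. The software that extracted the spot values is not given in the sources used here. The authors also deposited a value table, which likewise holds an intensity per probe and array. Its columns have medians of 25 in DMSO, at 5 µM and at 20 µM. Set against the scanner signal of the same array, each column followed a straight line that met 0 at a signal of 80.0 in DMSO, 77.3 at 5 µM and 77.6 at 20 µM. The trimmed means of the blank and negative control spots were 80.2, 77.4 and 77.8. The table thus holds linear values that are not centred per probe, with about the blank level taken off and 1 factor per array. With equal medians of 25, the arrays in it stand scaled to a common median. How the authors chose the blank level is not given in the sources used here.

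Each array had 24460 gene probes and 2996 control or empty spots. The spot signals were background-corrected with normexp in limma 3.58.1 under R 4.3.3, fitted on the signal of all spots with an offset of 50. The values were then taken to log2 and quantile normalized over the gene probes of the 3 arrays. The log2 ratios therefore stand for corrected signal plus an offset, and they understate the differences of dim genes. Tables were handled with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and plots were drawn with matplotlib 3.10.9.

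The design fixed before the data were examined called for the file's local background column where there was one. That column was not used for the main values. It rose with the spot's own signal, with Spearman correlations across spots of 0.971 in DMSO, 0.967 at 5 µM and 0.969 at 20 µM. Its median was 63.3 at the blank spots of the DMSO array and 8192 at the brightest spots of that array. The design's fallback, normexp on the spot signal alone, was used in its place. This was decided before any ratio between arrays had been computed, and the background column was kept as an added alternative. The results under it differed widely, as the part on processing describes.

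A probe was called detected on an array where its signal exceeded the mean plus 2 SD of that array's 480 blank and negative control spots, after dropping the top and bottom 5% of them. Spots that the file marks as not good, 0 in DMSO and 2 on each treated array, were not detected. A gene entered a comparison when it was detected on both arrays; a gene detected on 1 of them was given as an at least N-fold difference from the lowest detected level. Probe names came from the annotation of the array platform. Of the gene probes, 21707 had 1 gene symbol, 0 had several and 2753 had none. Of these, 21675 matched a current human gene record of assembly GRCh38.p14 through the gene identifier, and 0 symbols changed. No coordinates were used. The probes stood for 18639 genes, of which 2893 had several probes. The probe detected on most arrays and, among these, with the highest mean stood for the gene.

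With 1 array per group, no test was possible and no p-value is given. Differences are log2 ratios, and genes at least 2-fold apart were counted in each direction for the 3 comparisons of 20 µM against DMSO, 5 µM against DMSO and 20 against 5 µM. Nothing in such a design measures the spread between cultures. The technical spread was taken from matched control spots and from pairs of probes of the same gene. A set of 34 gene lists was fixed before the data were examined. Each list's median log2 ratio was placed among the medians of 10000 random lists of the same size, matched on mean expression in 20 bins, as a description of these arrays. The mark of a list as outside the middle 95% of its random lists was added after the values were seen.

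The genes named in the text were also chosen by a rule fixed before the data were examined. It took the 12 largest ratios each way for 20 µM against DMSO and the 6 largest each way for the other comparisons. It also took up to 4 members of every list with the largest ratios at 20 µM, all detected members of the list of Wnt targets, and up to 4 genes each way detected on 1 array only. Genes named outside this rule are said to be so.

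The steps were tested on simulated data for 20 µM against DMSO, with 200 of 24460 probes changed before background correction. Of probes changed 2-fold, 5.97% came out at least 2-fold apart, against 40.3% of probes changed 3-fold and 50.0% of those changed 4-fold. Among probes above the median signal the shares were 11.8%, 75.0% and 83.3%. Of 24260 unchanged probes, 0 were called. This says nothing about false calls in the data. The simulated spread, 0.067 per array from control spots, put the threshold out of reach, and it held no spread between cultures. Pairs of probes of the same gene gave a larger SD of 0.14 for a ratio. Simulated lists of 25 genes lay outside the middle 95% in 5 of 100 cases without a shift and in 97 of 100 cases with a shift of 0.10 on the log2 scale. Their genes were drawn at random from all detected genes, so the first share follows from the method and covers no genes that vary together. Some fixed lists had wider random lists, with a middle 95% from -0.12 to 0.11 for p53 targets at 20 µM. A shift of 0.10 can be missed there.

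The alternatives fixed before the data were examined were no background correction, subtraction of the blank mean with a floor of 1, a normexp offset of 16, median scaling, cyclic loess, the authors' value table, no detection filter, a stricter filter, the mean of a gene's probes, and thresholds of 1.5-fold and 3-fold. Normexp with the file's background column, and ratios centred within the 24 blocks of the array, were added after the files were seen.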

Results

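The series was made to find genes expressed differently in HT29 cells treated with a linderapyrone derivative and in cells given DMSO. Linderapyrone has been described as an inhibitor of Wnt signalling, the pathway through which beta-catenin drives transcription in most colorectal cancers. Gene expression was measured after 24 h in 3 groups of 1 array each, DMSO, 5 µM and 20 µM. The median spot signal was 117 in DMSO, 107 at 5 µM and 110 at 20 µM, against detection thresholds of 82.5, 79.4 and 80.2. Of 24460 gene probes, 21078 were detected in DMSO, 20927 at 5 µM and 20951 at 20 µM, which is 86.2%, 85.6% and 85.7%. No group had a replicate, so no difference below could be set against the spread between cultures, and the number of arrays limits the precision of every value. All log2 ratios are on the scale of corrected signal plus an offset of 50, which understates the differences of dim genes.

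The first comparison set 20 µM of the derivative against DMSO. The largest positive ratio belonged to DNAJB9, a chaperone of the endoplasmic reticulum (ER), whose normalized signal, with the offset, was 7.19-fold higher at 20 µM. Other genes of the ER were high as well, among them SDF2L1 at 4.13-fold and HERPUD1, which takes part in ER-associated degradation, at 3.01-fold. At the other end, ENC1 was 4.14-fold lower and DLGAP5, a spindle protein, 3.50-fold lower. Cyclin B1, encoded by CCNB1, was 2.93-fold lower. Of 16062 genes detected on both arrays, 71 were at least 2-fold higher and 52 at least 2-fold lower. Median scaling gave 52 higher and 74 lower, so the balance between the directions turned with the scaling. The authors' value table gave 231 higher and 266 lower.

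Besides the ER genes, the 12 largest positive log2 ratios included NIBAN1 at 2.39, ITPKA, a kinase of inositol trisphosphate, at 2.23, and SQSTM1, the autophagy receptor p62, at 1.93. They also included SEC24D, a coat protein of vesicles that leave the ER, at 1.69, ZFAND2A at 1.67, and GPAT3, an enzyme of triglyceride synthesis, at 1.67. GCLC, the catalytic subunit of the first enzyme of glutathione synthesis, had a ratio of 1.66, DNAJC25 of 1.62 and SDCBP2 of 1.56. The 12 most negative ratios included SOSTDC1, a secreted antagonist of BMP and Wnt ligands, at -1.63, and the homeobox gene MEIS2 at -1.32. LDHA, which encodes lactate dehydrogenase A, had a ratio of -1.29. The remaining genes at this end act in cell division: HMMR at -1.48, the mitotic kinase AURKA at -1.44, the checkpoint kinase BUB1 at -1.43, the kinetochore gene NDC80 at -1.39, CCNB2 at -1.30 and topoisomerase TOP2A at -1.25.

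All 24 detected members of the list of ER chaperones and unfolded protein response genes had ratios above 0 at 20 µM, and 5 were at least 2-fold higher. Their median log2 ratio was 0.57, above all 10000 random lists. DNAJC3, a co-chaperone that restrains the kinase PERK, had a ratio of 1.28. Of 31 members of the ATF4 and amino acid response list, 2 were at least 2-fold higher and 23 above 0, with a median of 0.37, above all random lists. These were DDIT3, which encodes the stress transcription factor CHOP, at 1.31 and the tryptophanyl-tRNA synthetase WARS1 at 1.24, while asparagine synthetase, ASNS, stood at 0.73 and AARS1 at 0.68. Of 23 NRF2 targets, 7 were at least 2-fold higher and 20 above 0, with a median of 0.46, above all random lists. After GCLC came SRXN1 at 1.43, the reductase gene AKR1B10 at 1.42 and HMOX1, heme oxygenase 1, at 1.16. A second probe of SRXN1 gave a ratio of 0.039.

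Interferon-stimulated genes were also higher at 20 µM than in DMSO: 24 of 28 had ratios above 0 and 2 were at least 2-fold higher, with a median of 0.46, above all random lists. IFI44L had a ratio of 1.19 and MX2 of 1.17, followed by HERC5 at 1.00, just short of 2-fold, and ISG20 at 0.94. IFIT3 went the other way, at -0.49. The ribosome biogenesis list had a smaller positive median of 0.17, at percentile 99.9 of its random lists, with 0 of 25 members 2-fold apart. Over the alternatives other than the background column this median fell to as low as 0.081. The list's largest ratios were those of NOP2 at 0.69, DDX21 at 0.46, RRP12 at 0.44 and POLR1B at 0.40.

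All 34 members of the mitosis list had ratios below 0 at 20 µM, and 14 were at least 2-fold lower. Their median of -0.84 lay below all random lists. Of 34 DNA replication genes, 30 were below 0, with a median of -0.27, below all random lists. The thymidylate synthase gene TYMS was the 1 member at least 2-fold lower, at -1.05, with UHRF1 at -0.85 and PCNA at -0.82, while CDC6, which loads the replicative helicase, was the 1 member at least 2-fold higher, at 1.05. Of 16 histone genes, 15 were below 0 and 2 at least 2-fold lower, with a median of -0.50, below all random lists. H2AC6 had a ratio of -1.06, H3-3B of -1.01, H2BC5 of -0.87 and H1-2 of -0.71. Over the alternatives other than the background column, H2AC6 came as near 0 as -0.98 and H3-3B as -0.94, both short of 2-fold. Oxidative phosphorylation genes were below 0 in 25 of 26 cases with 0 at least 2-fold apart, and their median of -0.27 lay at percentile 0.030. NDUFA2 stood at -0.65, ATP5F1A at -0.60, SDHA at -0.52 and SDHC at -0.45.

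Of 29 detected Wnt/beta-catenin targets, 3 were at least 2-fold lower at 20 µM, 0 were at least 2-fold higher and 21 were below 0. The median of -0.056 was at percentile 2.06, and lay at -0.19 under the stricter filter, at -0.046 without background correction and at -0.0044 under the scanner's background column. The genes at least 2-fold lower were ID2 at -1.23, BMP4 at -1.23 and the chloride transporter gene SLC12A2 at -1.15. SP5 stood at -0.91, SOX9 at -0.89, DKK1 at -0.75, MMP7 at -0.37 and CRIPTO at -0.35. Other targets, grouped after their values were seen, lay closer to 0, with AXIN2 at -0.20, ZNRF3 at -0.16, RNF43 at -0.10, ASCL2 at -0.056, EPHB3 at -0.041, LGR5 at -0.040 and NKD1 at -0.024. Their DMSO signals were between 91.8 for NKD1 and 160 for LGR5, within 2-fold of the detection threshold. In the authors' value table AXIN2 stood at -0.46, ZNRF3 at -0.39 and RNF43 at -0.31. There ASCL2 stood at -0.13, EPHB3 and LGR5 at -0.094 and NKD1 at -0.078. MYC had a ratio of 0.18, NOTUM 0.11, LEF1 0.097, VEGFA 0.087, FZD7 0.070, APCDD1 0.056, BAMBI 0.054 and PROX1 0.040. CD44 stood at -0.0089, CEMIP at -0.024, PPARD at -0.030, DKK4 at -0.081, CCND1 at -0.18 and JUN at -0.22. The 39 components of the Wnt pathway had a median of -0.0060 at percentile 25.4, with 0 members 2-fold apart. GSK3A at 0.43, AXIN1 at 0.42, TNKS2 at -0.41 and CSNK1E at 0.40 were the members farthest from 0, though another probe of GSK3A gave 0.093.

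**Figure D1:**
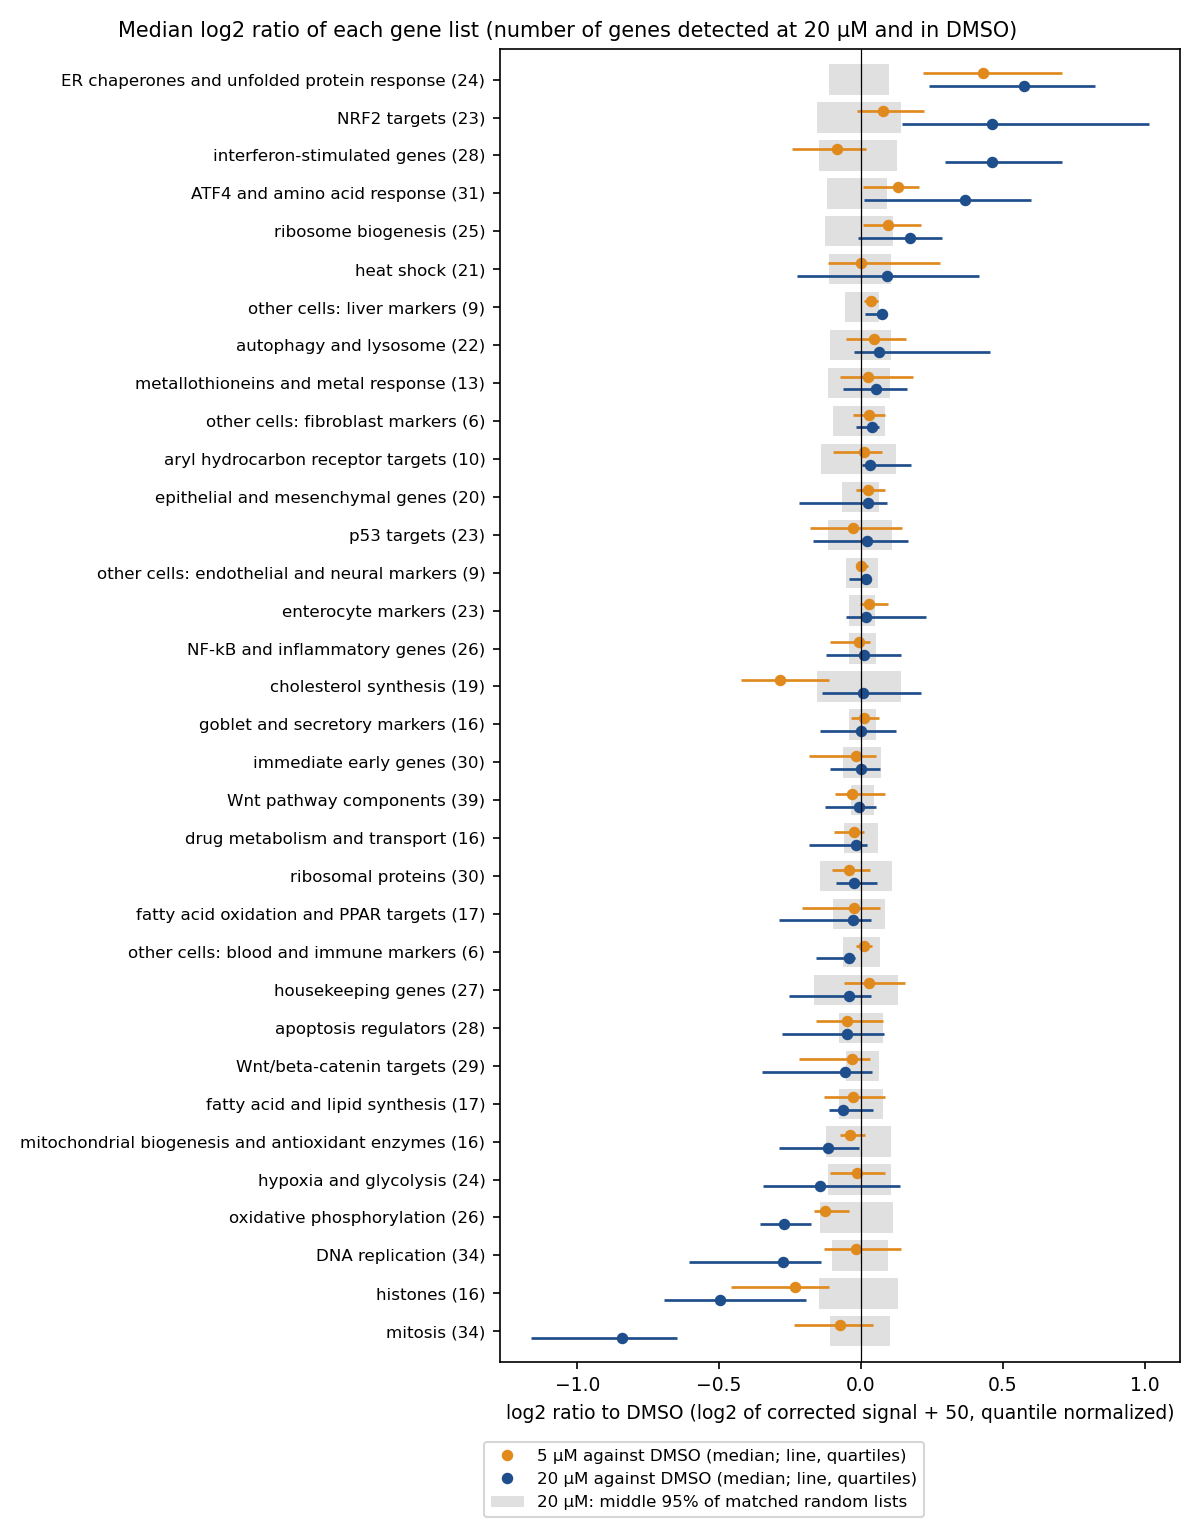
Median log2 ratio to DMSO of each gene list at 5 µM (orange) and 20 µM (blue), on the horizontal axis, with lines from the first to the third quartile over the list's detected genes and grey bars for the middle 95% of matched random lists at 20 µM. The ER list stood at 0.57 at 20 µM and 0.43 at 5 µM, the interferon list at 0.46 and -0.084, and the mitosis list at -0.84 and -0.073.

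Hypoxia and glycolysis genes had a median of -0.14 at 20 µM, at percentile 1.00, with LDHA the 1 of 24 members at least 2-fold lower, PKM at -0.53, NDRG1 at 0.50 and GPI at -0.45. The 9 detected liver markers were fixed as markers of other cells. Their median of 0.074 lay just above the 0.063 that bounds the middle 95% of their random lists. CPS1 at 0.18 was the member farthest from 0. DMSO signals of CPS1, CYP2E1 and TAT were 102, 88.9 and 102, near the detection threshold of 82.5, while that of SERPINA1 was 1359. The brightest empty position in DMSO had a signal of 134. The other lists for other cells lay inside the middle 95% of their random lists, with medians of 0.040 for 6 fibroblast markers, -0.042 for 6 blood and immune markers and 0.019 for 9 endothelial and neural markers. The list medians of p53 targets, at 0.020, and of apoptosis regulators, at -0.050, also lay inside that range. Among their members, the cell cycle inhibitor CDKN1A had a ratio of 0.84, BIRC5, the mitotic and anti-apoptotic protein survivin, of -1.17, CASP6 of -0.85 and FAS of -0.53. Enterocyte markers had a median of 0.019, with KRT20 at 0.92, and goblet and secretory markers one of 0.0012, with AGR2 at 0.50. Heat shock genes had a median of 0.091, with HSPA1A at 0.74 and HSPB1 at -0.59, and the autophagy and lysosome list one of 0.063, with GABARAPL1 at 0.95, WIPI1 at 0.94 and MAP1LC3B at 0.94.

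The technical spread was taken from repeated probes and spots. Over 2115 genes with 2 detected probes, the SD of a single log2 ratio was 0.14. The 24 matched spots of 1 positive control had an SD of 0.094, and those of another had 0.077. Their mean log2 ratios before normalization between arrays were -0.36 and -0.26. The SDs leave out such shifts of a whole array. Of 26 genes at least 2-fold apart that had another detected probe, 25 had the same direction on it and 10 were again at least 2-fold apart. When the background column of the scanner files was used for the correction, 878 genes were 2-fold apart. Of the 123 genes above, 33 were at least 2-fold apart the same way under it and 4 the opposite way, and the median of the NRF2 list turned to -0.17. The ER median shrank to 0.030, the interferon median to 0.063 and the mitosis median to -0.069. The log2 ratios of 2 probes of the same gene then had a correlation across genes of -0.0061, against 0.70 without that column; genes are not independent replicates.

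The second comparison set 5 µM against DMSO. At this dose the genes at least 2-fold higher were few, and most of them act in the ER. DNAJB9 was 4.62-fold higher, SDF2L1 3.67-fold, HERPUD1 2.80-fold, MANF, a secreted ER stress factor, 2.38-fold, FICD, which modifies the chaperone BiP, 2.19-fold, and DNAJC3 2.19-fold. SEC24D at 2.11-fold and SELENOK, an ER selenoprotein, at 2.06-fold completed the 8 genes at least 2-fold higher; SELENOK was named after its value was seen, to complete the set. The 1 gene at least 2-fold lower was DMP1, 2.29-fold lower, whose signal was 185 in DMSO and, at 86.6 and 87.7, close to the detection threshold at 5 and 20 µM. It was not called without background correction or under the stricter filter, which gave 6 and 8 higher genes and 0 lower. After DMP1 the lowest log2 ratios were those of H2AC6 at -0.90, IFIT3 at -0.90, ENC1 at -0.86, ID2 at -0.81 and H2BC5 at -0.77. There were 16075 genes detected on both arrays. Median scaling gave 5 higher and 4 lower genes, and the authors' value table gave 54 and 52.

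The ER list had 5 of 24 members at least 2-fold higher at 5 µM and 23 above 0, with a median of 0.43, above all random lists. All 16 histone genes were below 0, with a median of -0.23, below all random lists, and 0 were at least 2-fold lower. Cholesterol synthesis genes were below 0 in 16 of 19 cases, with a median of -0.29, below all random lists, against 0.0061 at 20 µM. Among them INSIG1, a sterol-regulated brake on the pathway, stood at -0.58, SC5D at -0.40 and CYP51A1 at -0.29. STARD4 went the other way, at 0.26. At 20 µM INSIG1 was still below DMSO, at -0.54, while CYP51A1 stood at 0.69, STARD4 at 0.65 and SC5D at 0.51. Leaving the background column aside, the cholesterol synthesis median lay between -0.49 and -0.27 over the alternatives. That of the histones lay between -0.44 and -0.23. Oxidative phosphorylation genes had a median of -0.13 at percentile 0.13, mitosis genes one of -0.073 at percentile 1.83, and interferon-stimulated genes one of -0.084 at percentile 2.05; median scaling gave -0.36, -0.31 and -0.31. The medians of the ATF4 list, 0.13, and of the ribosome biogenesis list, 0.096, lay above the middle 95% of their random lists, but turned to -0.099 and -0.053 under median scaling. The Wnt pathway components had a median of -0.032 at percentile 1.69, which turned to 0.065 under the stricter filter. The Wnt/beta-catenin targets had a median of -0.032 at percentile 5.75, with 0 of 29 members 2-fold apart, and NRF2 targets one of 0.077 at percentile 94.3. The NRF2 median lay between -0.14 and 0.086 over the alternatives other than the background column, so its sign turned. The SD of a single ratio from pairs of probes was 0.11 at this dose.

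**Figure D2:**
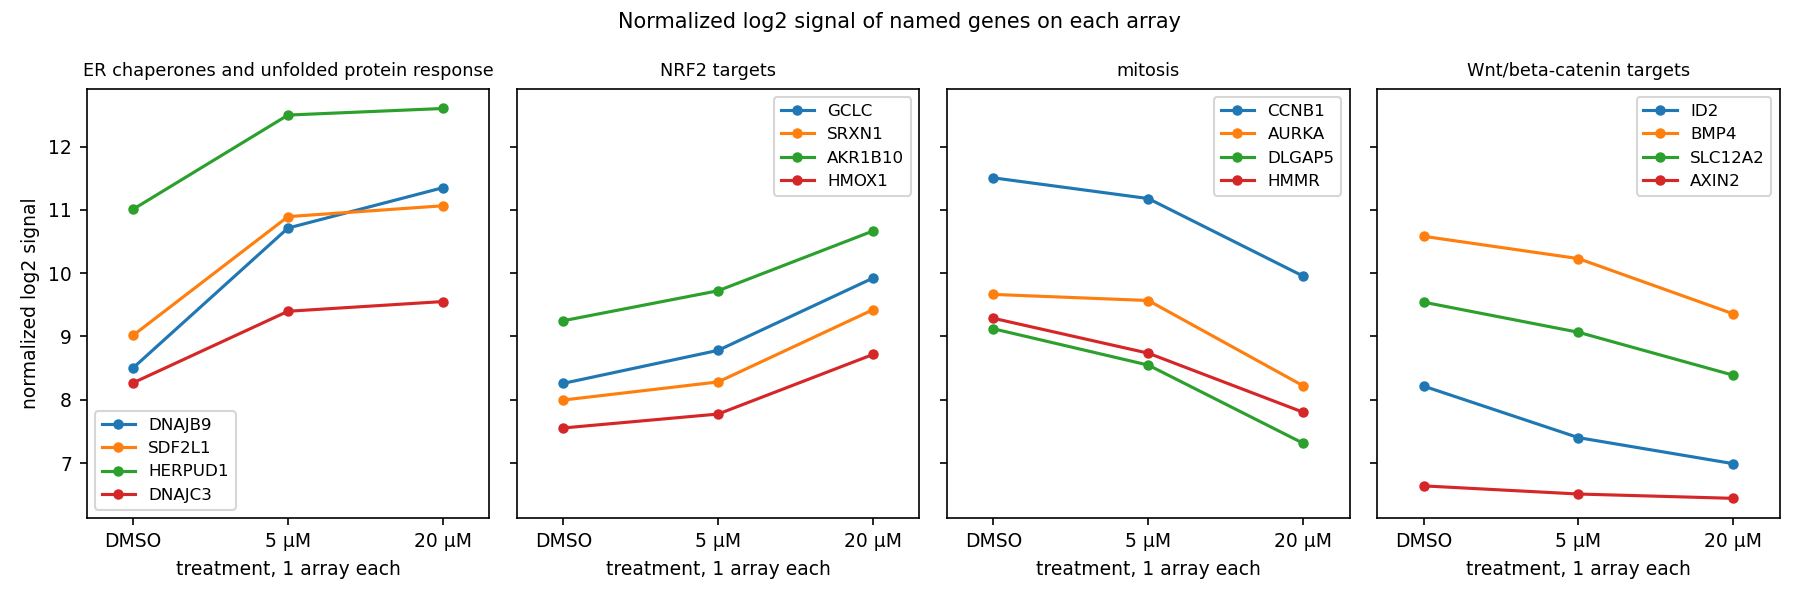
Normalized log2 signal (vertical axis) of 4 genes of each of 4 lists in DMSO, at 5 µM and at 20 µM, 1 point per array and no error bars because each group had 1 array. DNAJB9 lay 2.21 above DMSO at 5 µM and 2.85 at 20 µM, while AURKA lay 0.10 below DMSO at 5 µM and 1.44 below it at 20 µM.

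The third comparison set the doses against each other. ITPKA was 3.67-fold higher at 20 than at 5 µM, NIBAN1 2.96-fold and MX2 2.38-fold. SDCBP2 had a log2 ratio of 1.32. FADS3 and UBE2L6, which encodes an enzyme that attaches ISG15 to proteins, followed with log2 ratios of 1.20 and 1.18. The lowest log2 ratios were those of genes of cell division: KIF20A at -1.37, AURKA at -1.35, TOP2A at -1.35, the spindle factor TPX2 at -1.30, PTTG3P, a pseudogene of securin, at -1.29 and DLGAP5 at -1.23. Of 16036 genes detected on both arrays, 21 were at least 2-fold higher at 20 µM and 15 at least 2-fold lower. Median scaling gave 36 and 11. PTTG3P is a copy of another gene, so its probe may also bind the transcript of that gene. The securin gene PTTG1, named outside the rule, had log2 ratios of -0.63 for 20 against 5 µM and -0.37 for 5 µM against DMSO. Those of PTTG3P were -1.29 and 0.13.

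All 28 interferon-stimulated genes had higher values at 20 than at 5 µM, and 3 were at least 2-fold higher, with a median of 0.57, above all random lists. Of 24 NRF2 targets, 23 were higher and 3 at least 2-fold higher, with a median of 0.40, above all random lists; the ATF4 list had a median of 0.26, also above all of them. Cholesterol synthesis genes had a median of 0.17 at percentile 99.9, and the autophagy and lysosome list one of 0.11 at percentile 99.6. Of 34 mitosis genes, 33 were lower and 11 at least 2-fold lower, with a median of -0.75, and 32 of 34 DNA replication genes were lower, with a median of -0.28; both medians lay below all random lists. Histones stood at -0.16, oxidative phosphorylation at -0.15 and the Wnt/beta-catenin targets at -0.072, at percentiles 0.30, 0.43 and 0.13. The housekeeping list had a median of -0.12 at percentile 2.49, and the 6 blood and immune markers one of -0.13 at percentile 0.020. These became -0.0036 under median scaling and -0.018 without the detection filter. In the ER list, 17 of 24 members were higher at 20 than at 5 µM and 0 were 2-fold apart, with a median of 0.091 at percentile 99.3.

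Both doses were compared with the same DMSO array, so part of any likeness between them may come from that array. All 9 genes at least 2-fold from DMSO at 5 µM were at least 2-fold from it in the same direction at 20 µM, 8 higher and 1, DMP1, lower. Independent lists of these sizes would share 0.036 higher and 0.0033 lower genes, numbers that leave the shared DMSO array out. Simulated arrays without an effect shared 0. This decides nothing, because their spread of 0.065 per array put the 2-fold threshold out of reach. Across 15920 genes the log2 ratios of both doses to DMSO had a Pearson correlation of 0.67, against 0.50 in the simulation, and a covariance of 0.0234 against 0.00422; 72.6% of the genes had the same sign at both doses, against 66.7%. Genes are not independent replicates, and the simulation used 1 spread for all genes, taken from the quartiles of the 5 µM ratios. Larger errors of single genes on the shared DMSO array are therefore not in it.

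**Figure D3:**
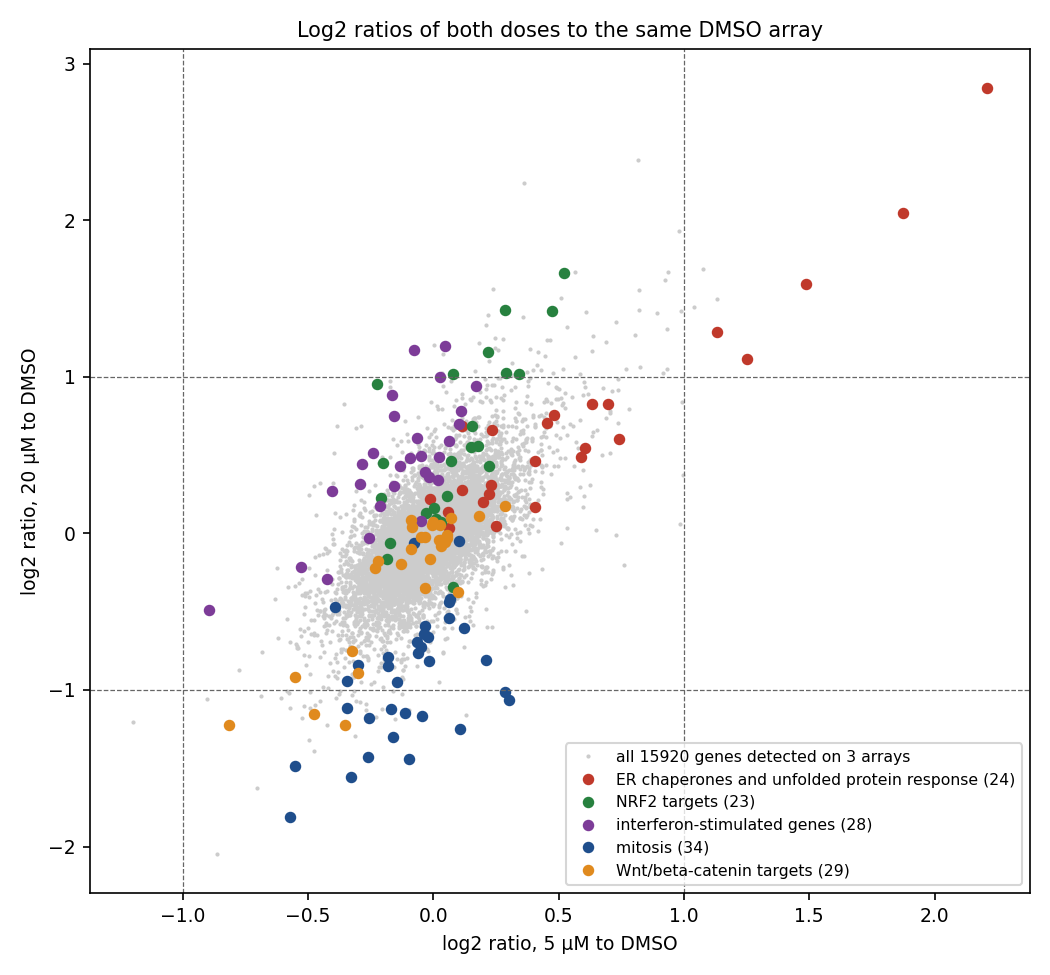
Log2 ratio to DMSO at 20 µM (vertical axis) against that at 5 µM (horizontal axis) for the 15920 genes detected on all 3 arrays, with dashed lines at 2-fold and 5 gene lists in colour. Of the ER list 5 genes lay beyond 2-fold at both doses, while the mitosis genes had a median of -0.84 at 20 µM and of -0.073 at 5 µM.

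Genes detected on 1 array of the main pair have only a bound. ERO1B, an oxidase of the ER, was detected at 20 µM and not in DMSO, and was at least 1.79-fold higher. SPATA3 was at least 1.47-fold higher, KRT39 at least 1.22-fold and PLEKHG2 at least 1.19-fold. In the other direction OR7E130P was at least 1.29-fold lower at 20 µM, MTUS2 at least 1.24-fold, SUCNR1 at least 1.21-fold and ADGRG7 at least 1.14-fold. In all, 256 genes were detected at 20 µM and not in DMSO, and 333 in DMSO and not at 20 µM. The same threshold was exceeded by 11.5% of empty positions at 20 µM and 13.1% in DMSO. Detection on 1 array alone therefore need not mean expression. The brightest empty positions had signals of 224 and 134. The bounds compare the measured signals and include no spread between arrays.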

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

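The tests on single cultures and on position were chosen after the results were seen, as was the scanner's background column; the limit for the normalization test was set before its values were computed. Each gene below had opposite signs at 5 and 20 µM, both beyond 2 SDs of a single ratio from pairs of probes, a rule set after the values were seen. With 1 array per dose these differences were not tested.

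Interferon-stimulated genes stood apart between the doses: their median log2 ratio to DMSO was 0.46 at 20 µM and -0.084 at 5 µM, a difference of 0.55. UBE2L6, which acts in the same response, had a ratio of 20 to 5 µM of 1.18. Position is argued against as the whole cause of the shift at 20 µM. The spots within 2 columns and rows around the members had a median ratio of 0.0029, and the highest value around any member was 0.062. The spots around them at 5 µM were not examined. Centring within blocks was tried first for position and decided nothing. Normalization between arrays is argued against as the whole cause of the difference between doses. The smallest difference under median scaling, cyclic loess and the authors' value table was 0.564. Under the scanner's background column the pattern was nearly absent, with medians of 0.063 at 20 µM and 0.043 at 5 µM and a median ratio of 20 to 5 µM of 0.10. An induction of these genes by the higher dose may underlie the pattern as a hypothesis, but it cannot be told apart from a difference between single cultures, such as density, because each group had 1 array.

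CYP51A1 and SC5D, enzymes of sterol synthesis, were below DMSO at 5 µM and above it at 20 µM, with ratios of 20 to 5 µM of 0.97 and 0.91. The mitotic genes TPX2 and KIF20A went the other way, with ratios of 20 to 5 µM of -1.30 and -1.37. Their ratios of 5 µM to DMSO, 0.29 and 0.30, lay little above the limit of 0.22. Median scaling took the mitosis median at 5 µM from -0.073 to -0.31, so the signs of these genes at 5 µM may depend on the scaling. Among probes without a gene symbol, which no comparison used, 2293 were detected at 20 µM and in DMSO; 3 were at least 2-fold higher at 20 µM and 0 at least 2-fold lower. Of 2412 empty positions, 278 exceeded the detection threshold on the 20 µM array, against 317 in DMSO and 444 at 5 µM. The brightest empty position on the 20 µM array had a signal of 224.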

How the results depend on the processing

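The background column and the centring within blocks were tried after the files were seen; the other alternatives were fixed before. The number of genes called apart moved most with the fold threshold and with how background was handled. The counts for 20 µM against DMSO, 5 µM against DMSO, 20 against 5 µM and both doses were 123, 9, 36 and 9. Without background correction they were 93, 6, 29 and 6. They became 491, 112, 238 and 49 with the blank mean subtracted, 208, 21, 70 and 15 with an offset of 16, and 497, 106, 244 and 44 in the authors' value table. A 1.5-fold threshold gave 607, 76, 289 and 58, and a 3-fold threshold 14, 2, 1 and 2. The scanner's background column gave 878, 657, 793 and 304. In all, 24 counts moved by over 1.5 times and 28 did not. Of 80 log2 ratios of named genes that were at least 2-fold, 80 stayed so in the authors' table and under cyclic loess, 76 under median scaling, 77 with the mean of probes, 72 without background correction and 30 under the background column. Signs of these 80 turned under the background column alone, where 57 kept theirs; the stricter filter left 78 of them to compare. No paired analysis was possible because each group had 1 array. Signal over background limits dim genes most: in simulated data 0 of 33 probes below the median signal that were changed 2-fold reached the threshold.

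Some medians lay outside the middle 95% of their random lists. Leaving the background column aside, these kept their sign in 12 of 12 lists for 20 µM against DMSO. They kept it in 6 of 9 for 5 µM against DMSO and in 13 of 13 for 20 against 5 µM. Lists of genes drawn at random would lie outside that range in 1.7 of 34 cases. That number concerns lying outside and not signs. Genes of a fixed list may vary together, so it is no measure of chance for these lists. At 5 µM the ATF4 median turned to -0.099 and the ribosome biogenesis median to -0.053 under median scaling, and that of Wnt components to 0.065 under the stricter filter; the cause was not tested. Medians that kept their sign also moved. At 5 µM against DMSO, median scaling took oxidative phosphorylation from -0.13 to -0.36, mitosis from -0.073 to -0.31 and interferon-stimulated genes from -0.084 to -0.31. For 20 against 5 µM it took housekeeping genes from -0.12 to -0.0036 and oxidative phosphorylation from -0.15 to -0.030, and without the detection filter blood and immune markers went from -0.13 to -0.018. The Wnt/beta-catenin targets at 20 µM against DMSO lay between -0.19 under the stricter filter and -0.046 without background correction, and DNA replication genes between -0.53 in the authors' table and -0.23.

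Under the background column the main list medians for 20 µM against DMSO shrank, to 0.030 for the ER list, 0.063 for interferon-stimulated genes, -0.069 for mitosis, -0.17 for histones and -0.0044 for Wnt/beta-catenin targets, against 0.57, 0.46, -0.84, -0.50 and -0.056. List medians turned for NRF2 targets at 20 µM, to -0.17. At 5 µM they turned for mitosis to 0.15, cholesterol synthesis to 0.016, interferon-stimulated genes to 0.043, Wnt components to 0.020, the ATF4 list to -0.0020 and ribosome biogenesis to -0.042. For 20 against 5 µM they turned for Wnt/beta-catenin targets to 0.0066, the ER list to -0.028, NRF2 targets to -0.020, autophagy and lysosome to -0.042 and oxidative phosphorylation to 0.041.

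Under the background column, of 128 named ratios of 20 µM to DMSO below 2-fold, 53 changed sign, among them PCNA, from -0.82 to 4.60. Of those at least 2-fold, the log2 ratios of 20 µM to DMSO turned for HERPUD1 to -0.054, SDCBP2 to -0.19, FICD to -0.022, SRXN1 to -0.33, AKR1B10 to -0.21, LCN2 to -0.24, MX2 to -0.27, HMOX1 to -0.25 and ESRP1 to -1.82. They turned for EGR1 to 0.35, SLC12A2 to 0.42, PTTG3P to 0.94, BIRC5 to 0.14, TOP2A to 0.22, LDHA to 1.60, NDC80 to 0.85, BUB1 to 0.50 and ENC1 to 0.67. Of the other ratios at least 2-fold, that of 5 µM to DMSO turned for SDF2L1 to -1.56, and that of 20 to 5 µM for SRXN1 to -0.26, CCNB2 to 0.51, BUB1 to 0.34 and ENC1 to 0.30. That column rises with the spot's own signal. The ratios of 2 probes of the same gene, which share no spot, had a correlation of -0.0061 across 2115 genes under it for 20 µM against DMSO, against 0.70 in the main values, 0.71 under median scaling and 0.56 in the authors' table.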

Other observations

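Of the tests below, those on the offset, on position and on single cultures were chosen after the results were seen. Of the 71 genes at least 2-fold higher at 20 µM, 50 were in none of the gene lists, and of the 52 lower genes, 30; those named in this paragraph were picked after their values were seen. DERL2 and the selenoprotein gene SELENOS, both of ER-associated degradation, had log2 ratios of 1.06 and 1.40, SELENOK of 1.45 and SERP1, which stabilises ER membrane proteins, of 1.27. EIF2AK3, which encodes the stress kinase PERK, stood at 1.02 and the ER reductase gene DNAJC10 at 1.03. At 5 µM the same genes had ratios of 0.83, 0.89, 1.04, 0.81, 0.58 and 0.37. The Notch ligand JAG1 stood at 1.40 and the CDK inhibitor gene CDKN2B at 1.25, against 0.22 and 0.25 at 5 µM. Among the lower genes in no list were the oxidase gene NOX1 at -1.03, EDN1, which encodes endothelin 1, at -1.01 and the homeobox gene HOXB7 at -1.18.

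Lists not described so far lay inside the middle 95% of their random lists at 20 µM against DMSO. Their medians were 0.033 for aryl hydrocarbon receptor targets, -0.018 for drug metabolism and transport, -0.063 for fatty acid and lipid synthesis and -0.027 for fatty acid oxidation and PPAR targets. The medians were 0.011 for NF-kB and inflammatory genes, 0.024 for epithelial and mesenchymal genes, 0.0010 for immediate early genes and 0.055 for metallothioneins and metal response. Ribosomal proteins had a median of -0.023, housekeeping genes of -0.043 and mitochondrial biogenesis and antioxidant enzymes of -0.12. Single members lay farther out. LCN2, an iron-binding protein of inflamed epithelium, was 2.55-fold higher. The ERK phosphatase gene DUSP5 had a ratio of 1.24, the splicing regulator ESRP1 of 1.08 and the lipid droplet gene PLIN2 of 0.95. EGR1, an immediate early transcription factor, stood at -1.10, HADHA, of fatty acid oxidation, at -0.82 and NFKBIA at -0.62. FOS had a ratio of -0.78 on the chosen probe and of 0.24 on another.

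The ER list was already near its 20 µM level at 5 µM, with a median 74.7% of that at 20 µM, while the mitosis list reached 8.62%. Under median scaling, cyclic loess and the authors' value table the ER share was at least 66.5% and the mitosis share at most 32.3%, which argues against normalization as the whole cause. A scanner ceiling is argued against as well, since the median signal of the ER members at 5 µM was 2.02% of the brightest spot. A candidate explanation, as a hypothesis, is that the ER response needs less of the derivative than the loss of mitotic transcripts. With 1 array per group, a difference between single cultures cannot be told apart from it.

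Within the Wnt/beta-catenin targets, the 6 lowest genes (ID2, BMP4, SLC12A2, SP5, SOX9 and DKK1) had a median log2 ratio of -1.03 at 20 µM, while 10 genes that include feedback regulators such as AXIN2 had one of -0.040; both sets were picked after the values were seen. Position on the array is argued against, since the spots within 2 columns and rows around the 6 genes had a median ratio of 0.050. In the authors' table, which has no offset, the 6 genes had a median of -1.34, against 0.17 for MYC, 0.083 for VEGFA, -0.24 for CCND1, -0.26 for JUN and -0.43 for MMP7, which were also picked after their values were seen. In that table the median of the 10 genes was -0.094, with AXIN2 at -0.46, ZNRF3 at -0.39 and RNF43 at -0.31 but LEF1 at 0.45 and APCDD1 at 0.67. Of the 10 genes, 6 had DMSO signals within 50 units of the blank spots, so for these an effect of the offset, which may hide a change, cannot be told apart from an absent response.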
